A study of Homo sapiens with 6 samples.

How the data were processed

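The data are gene expression arrays of NB4 cells, a human line established from acute promyelocytic leukaemia, with and without infection by Anaplasma phagocytophilum. The 6 arrays form 2 groups of 3, control and infected, as their titles state, and the labels place the RNA at 4 h post-infection. Per the labels' protocols, RNA was extracted with TRI reagent and cleaned with RNeasy columns, and Affymetrix Human Genome U133 Plus 2.0 arrays were quantified with Microarray Suite 5.0 (MAS 5.0) at default parameters and made comparable by global scaling. Per the labels, a detection p-value was used to call transcripts present. Detection calls were not used here, and a test between the groups is not given in the sources used here.

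The deposited values are signal intensities per probe set on a linear scale, 1 column per array. The mean of each array without its highest and lowest 2% of probe sets was 500.07, which is how a scaling target of 500 shows in the values. Each array held 54675 probe sets, of which 62 are Affymetrix control probe sets and were left out of the tests. Between 12 and 44 values per array lay under a signal of 1 and were set to 1 before the log2 transformation, and no pseudocount was added. Array data have no count depth, so their number limits the precision. No label says whether the 3 arrays of a group came from separate cultures, and p-values then measure only the spread between these arrays, which may be technical.

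Probe sets whose mean log2 signal over the 6 arrays lay above the median of all probe sets (a signal of 72.9) were tested, 27306 in number. Of these, 22201 had 1 gene symbol in the platform annotation given with the data, 1102 had several and 4003 had none, and genes were named only from probe sets with 1 symbol. No symbol changed when updated through its gene identifier. A gene was represented by its tested probe set with the highest mean log2 signal, which gave 11633 genes. Infected and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), adjusted by the Benjamini-Hochberg method over all probe sets tested and called at an adjusted p under 0.05. Fold changes are differences of mean log2 signal, and group levels are arithmetic means of the signal.

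A set of 30 gene lists was fixed before the data were examined, together with the tests, the alternatives and the rule for naming genes. The lists cover the NADPH oxidase, inflammatory and interferon genes, Toll-like receptor signalling, adhesion, granule and myeloid genes, the cytoskeleton, sterols, apoptosis, stress responses, metals, vesicles and lysosomes, the cell cycle, ribosomes, energy metabolism, chromatin silencing, the proteasome and markers of 5 other cell types. The 28 lists with at least 5 measured members were tested with camera in limma, with the preset inter-gene correlation of 0.01 and adjustment over the lists. An estimated correlation was an alternative, and fry was run beside it. Named genes were to be the 12 largest increases and 12 largest decreases that passed the threshold without overlap of the groups, up to 4 members with the smallest adjusted p from each list, and 16 genes fixed in advance. Because fewer than 5 genes met the first criterion, the 5 genes with the smallest p in each direction were named as not passing. Of the 16 fixed genes, 3 were not analysed here. The ratio of the 3' to the 5' control probe set of GAPDH and of ACTB was compared with an exact permutation test.

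The titles number the arrays 1 to 3 in both groups. The deviations of same-numbered arrays from their group means correlated at 0.254, 0.147 and 0.404 across probe sets for numbers 1, 2 and 3, and 5 of the 6 arrays correlated best with their own number. By the criterion used (every pair above 0.1), the numbers were taken to pair the arrays. The criterion is weak, because infected array 2 correlated more with control array 1 (0.219) than with control array 2. This pairing comes from the data and not from a statement in the labels. The control and infected array of a number are called a pair, and the fit with the number as a block is given beside a result where it changed it.

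The tests were checked on simulated data for this comparison, with 27306 probe sets of which 100 were changed 2-fold and 100 were changed 4-fold. With noise independent between arrays, the fit without a block recovered 47% of the 2-fold and 79% of the 4-fold changes. With noise shared within a number it recovered 24% and 58%, and the fit with the block recovered 73% and 89%. Unchanged probe sets called numbered 0 without and 14 with the block under shared noise, and 5 and 9 under independent noise. The shared part was the observed mean deviation of each number's arrays, which also holds unshared noise. The gain from the block may therefore be larger in the simulation than in the data. In the same simulations the measured members of the inflammatory list itself were shifted by 0.3 on the log2 scale among 11633 genes. Camera at the preset correlation called this list (adjusted p = 3.06e-11 with independent and 2.19e-19 with shared noise) and 0 of the other 27 lists. With an estimated correlation the adjusted p of the shifted list was 0.0335 with independent noise and 0.102 with shared noise. A list that is not called at that setting may therefore still have shifted. Apart from the part shared within a number, which cancels between the groups, the noise was drawn separately for each gene. The 0 calls of other lists therefore say nothing about lists whose members move together.

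Alternatives covered other normalizations (quantile, median centring, cyclic loess), other filters, pseudocounts of 16 and 64, other variance models, array weights, the replicate block, probe sets that can match several transcripts, a 2-fold minimum, other list settings and leaving out each array. After the data were examined, fits without both number 3 arrays and fits that combine the block or a left-out array with another setting were added.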

Results

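NB4 is a human cell line established from acute promyelocytic leukaemia. Anaplasma phagocytophilum is a bacterium that lives inside neutrophils, and the arrays compare NB4 cells carrying it with control cells at 4 h post-infection, 3 arrays in each group, to show how infection affects the transcripts of the host cell. Each array measured 54675 probe sets as MAS 5.0 signals scaled to the same trimmed mean. The median signal lay between 83.9 (control array 2) and 98.9 (infected array 3), and the 10 brightest probe sets held between 1.23% and 1.52% of an array's total signal.

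At camera's preset correlation, the lists of inflammatory and oxidative stress genes were called as higher in infected cells, while no single gene passed the test. With an estimated correlation 0 lists were called, but that setting also missed a simulated shift of 0.3 when noise was shared within a number. Of the 10 splits of the arrays into 3 and 3, the real one included, 7 called at least as many lists. The list of NF-kB targets, cytokines and chemokines rose: 29 of its 34 measured members had higher means in infected cells, with a median log2 difference of 0.13 (quartiles 0.05 and 0.38) and a mean of 0.27 (camera in limma, adjusted p = 2.31e-05, or adjusted p = 0.666 with an estimated correlation). The oxidative stress list rose, with 19 of 27 members higher, a median of 0.05 (quartiles -0.03 and 0.24), a mean of 0.13 and an adjusted p of 0.0218 (adjusted p = 0.727 with an estimated correlation), although its median was -0.02 when each array was centred on its median. That centring lowers all differences alike, the list medians by 0.0678, so it turns any median between 0 and that value negative. Neither list passed in fry, where the adjusted p was 0.754 for both (0.968 for change in either direction). HMOX1, which encodes the haem-degrading enzyme heme oxygenase 1, had a signal of 856 ± 311 in control and 1905 ± 608 in infected cells (SD, n = 3), a 2.23-fold difference. GATA2, a transcription factor of blood progenitors, stood at 1318 ± 63.8 and 2236 ± 560 (SD, n = 3), a 1.66-fold difference.

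Among 27306 probe sets, limma called 0 at an adjusted p under 0.05, and the smallest adjusted p was 1. At an unadjusted p under 0.05 there were 568 probe sets, 281 higher and 287 lower in infected cells, or 2.08% of those tested. Centring each array on its median made this split 151 higher and 464 lower. With the replicate number as a block, 0 probe sets were called again (smallest adjusted p 0.131) and 1790 had an unadjusted p under 0.05, or 6.56%. The groups did not overlap for 984 probe sets higher and 1024 lower in infected cells, 7.35% of those tested. Chance gives 10% if the 6 arrays are exchangeable, which arrays paired by number would not be.

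The number 3 arrays stood apart from the other 4. On the first principal component, which held 42.4% of the variance, control array 3 lay at 45.2 and infected array 3 at 75.02, and the other arrays lay between -38.3 and -13.4. They also differed from each other. On the second component (19% of the variance) control array 3 lay at -52.03 and infected array 3 at 42.32, the opposite extremes of the arrays. The log2 ratio of the 3' to the 5' control probe set, a sign of RNA degradation, was -0.09 ± 0.05 in control and -0.04 ± 0.06 in infected arrays for GAPDH (SD, n = 3, exact permutation p = 0.2) and 0.45 ± 0.07 and 0.57 ± 0.11 for ACTB (SD, n = 3, exact permutation p = 0.2). These two-sided tests of 3 against 3 arrays cannot give a p below 0.1. Neither ratio was highest in a number 3 array.

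**Figure D1:**
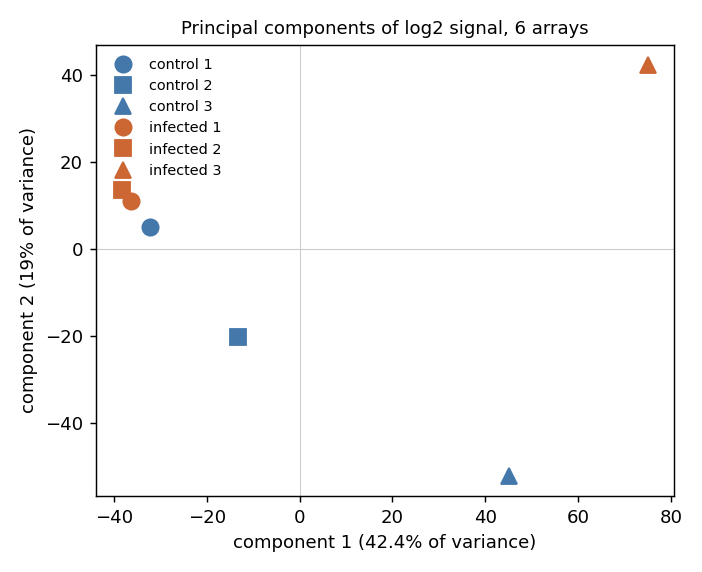
First and second principal components of the log2 signals of the tested probe sets, 1 point per array, with colour for the group and marker shape for the array number. Control array 3 (45.2) and infected array 3 (75.02) lie apart from the other 4 arrays on component 1.

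The inflammatory list was called in each of the 6 fits that left out 1 array and in 0 of them with an estimated correlation. Its adjusted p ranged from 2.39e-06 to 0.879 over all 28 alternatives. Its mean log2 difference was 0.36 in pair 1, 0.31 in pair 2 and 0.15 in pair 3 (medians 0.35, 0.19 and 0.02), and 13 members were higher in all 3 pairs while 0 were lower in all 3. No member passed limma's threshold over all probe sets. Adjusted over the list alone, 0 passed without a block and 1 with the replicate block. CXCL10, a chemokine induced by interferons, had the largest difference of the members named by rule, 2.55 ± 0.82 on the log2 scale (SE), but with low signals of 45.3 ± 41.1 in control and 183 ± 58.5 in infected cells (SD, n = 3). Its pairs differed by 2.59, 4.64 and 0.41, and with 1 array left out the difference ranged from 1.59 (without control array 2, whose signal was 8) to 3.33. The neutrophil chemokine CXCL8 had signals of 1546 ± 188 and 1984 ± 58.6 (SD, n = 3), or 0.37 ± 0.14 on the log2 scale (SE). NFKB1, a subunit of NF-kB, differed by 0.51 ± 0.19 and TNFAIP2 by 0.65 ± 0.22 (SE), although 1 of the 2 probe sets of TNFAIP2 pointed the other way. The cytokines TNF (0.06 ± 0.23) and IL1B (0.07 ± 0.21) lay within their errors.

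The oxidative stress list was led by HMOX1 (1.15 ± 0.30 on the log2 scale, SE), SLC7A11, the cystine transporter (0.56 ± 0.19), TXNRD1, thioredoxin reductase 1 (0.33 ± 0.12), and ME1, malic enzyme 1 (0.27 ± 0.13), each with an adjusted p of 1 in limma. Of its members, 6 were higher in all 3 pairs and 5 were lower in all 3, and whether a few members carry its call was not tested. The list's mean difference was 0.19 in pair 1, 0.16 in pair 2 and 0.02 in pair 3 (medians 0.09, 0.01 and 0.00). HMOX1 followed the same course, with 1.84, 1.62 and 0.00, as did SLC7A11 with 0.89, 0.69 and 0.09, where 1 of its 3 probe sets pointed the other way. Without both number 3 arrays, a fit chosen after the data were examined, HMOX1 was the 1 gene called (log2 difference 1.73, limma adjusted p = 0.0184). Adjusted over the list alone, 0 members passed without a block, 3 with the replicate block and 4 without the number 3 arrays. The list's call was lost without control array 1 (adjusted p = 0.256), control array 2 (adjusted p = 0.187) or infected array 3 (adjusted p = 0.165), and its range over the 6 fits without 1 array was 0.01 to 0.09 in the median log2 difference. Over all 28 alternatives its adjusted p ranged from 0.000222 to 0.879.

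**Figure D2:**
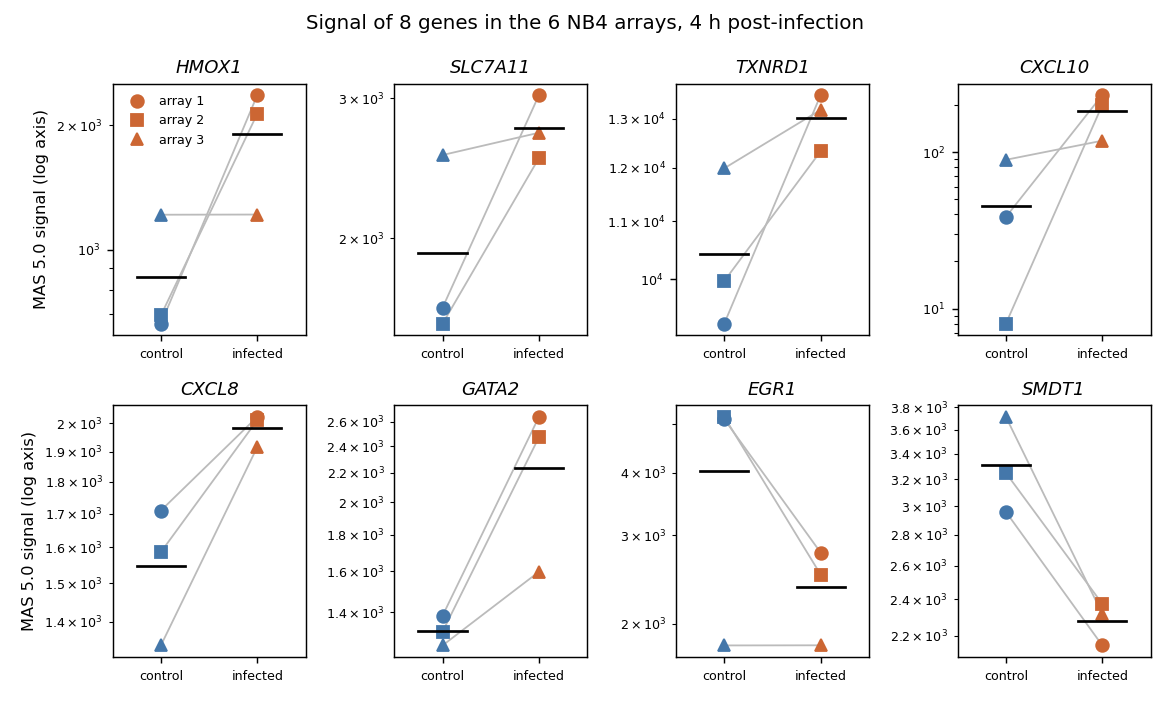
Signal (log axis) of 8 genes in control and infected arrays, 1 point per array with marker shape for the array number, grey lines joining the arrays of a number and black bars for the arithmetic mean of 3 arrays. HMOX1 and EGR1 differ between the groups in pairs 1 and 2 and lie level in pair 3 (log2 differences of 0.00 in both), and no gene passed the adjusted test with all 6 arrays.

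The genes with the smallest p in each direction did not pass the test. Besides HMOX1 and GATA2, those higher in infected cells were MIR1915HG (1.52 ± 0.36, log2 difference and SE), SENCR (2.30 ± 0.66, or 1.73 to 3.04 with 1 array left out, from control signals of 28.1, 98.4 and 16) and SPATA32 (1.97 ± 0.46). Those lower were SMDT1, a subunit of the mitochondrial calcium uniporter, at 3308 ± 382 in control and 2280 ± 117 in infected cells (SD, n = 3), COG4 (-1.78 ± 0.47), EEF2KMT (-1.86 ± 0.45), MAPK11 (-1.75 ± 0.43) and ONECUT3 (-1.71 ± 0.44). Apart from HMOX1, GATA2 and SMDT1, the mean signals of these genes lay between 39.7 and 282. The infected means of EEF2KMT (39.7), ONECUT3 (42.8) and MAPK11 (60.4) lay below the filter signal of 72.9. So did the control means of SENCR (47.5) and MIR1915HG (64.1), and without detection calls the sizes of these differences are uncertain. SMDT1 was lower in all 3 pairs, by log2 differences of -0.46, -0.45 and -0.68, and both of its probe sets pointed the same way. GATA2 was higher in all 3 pairs, by 0.93, 0.91 and 0.35, as were its 3 probe sets taken over the groups.

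Interferon-stimulated genes had lower means in infected cells for 25 of 33 measured members and higher means for 8, with a median log2 difference of -0.12 (quartiles -0.26 and -0.01) and an adjusted p of 0.0973 (camera). Of them, 12 were lower in all 3 pairs and 3 were higher in all 3. ISG15, a ubiquitin-like interferon-induced protein, stood at 1107 ± 71.7 in control and 907 ± 30.8 in infected cells (SD, n = 3). IFI16, a DNA sensor, differed by -0.45 ± 0.22 on the log2 scale (SE), SAMD9L by -0.84 ± 0.41 and IFIT1 by -1.72 ± 0.87, the last from low signals of 168 ± 75.6 in control and 78.1 ± 89.0 in infected cells (SD, n = 3). IFIT1 differed by -2.31, -0.29 and -2.55 in pairs 1, 2 and 3, by -0.84 without infected array 3 and by -2.69 without infected array 2. The list did not pass the test with all arrays and was called as lower without control array 3 (adjusted p = 0.0158, or adjusted p = 0.515 with an estimated correlation, range over the alternatives 0.0158 to 0.879).

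The respiratory chain list had 26 of 37 members lower, with a median of -0.05 (quartiles -0.12 and 0.02) and an adjusted p of 0.16. It was called as lower with the replicate number as a block (camera, adjusted p = 0.0252, or adjusted p = 0.822 with an estimated correlation) and without infected array 3 (adjusted p = 2.21e-07, or adjusted p = 0.842 with an estimated correlation, range over the alternatives 2.21e-07 to 0.985). Its mean difference was -0.09 in pair 1, -0.13 in pair 2 and 0.05 in pair 3. NDUFB5, a subunit of complex I, had the smallest p among its members, at -0.24 ± 0.09 (log2 difference and SE), followed by NDUFA1 (-0.19 ± 0.12) and NDUFS1 (-0.23 ± 0.17), where 3 of 4 NDUFS1 probe sets were lower. Ribosomal proteins had a median of 0.03, but of -0.01 after quantile normalization and -0.04 with median centring (adjusted p = 0.322). Their mean was -0.02 in pair 1, -0.09 in pair 2 and 0.20 in pair 3, and the list was called as higher without infected array 2 (adjusted p = 6.07e-08) and as lower without infected array 3 (adjusted p = 0.0171). With an estimated correlation these were 0.63 and 0.842, and the range over the alternatives was 6.07e-08 to 0.982. RPL22 (0.08 ± 0.10) and RPS23 (0.09 ± 0.09, with 1 of its 2 probe sets in the other direction) lay within about their errors.

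The NADPH oxidase makes superoxide in phagocytes. Of its 7 measured members 4 had higher and 3 lower means, with an adjusted p of 0.835 and a median of 0.02 that was -0.04 with median centring. CYBB, the catalytic subunit, stood at 2812 ± 108 in control and 3380 ± 519 in infected cells (SD, n = 3), 0.25 ± 0.14 on the log2 scale (SE), and 1 of its 2 probe sets pointed the other way. RAC2, the regulatory GTPase, stood at 7154 ± 381 and 7071 ± 500 (SD, n = 3). NCF1 differed by 0.15 ± 0.23 and CYBA by -0.21 ± 0.19 (log2, SE). Among 21 receptors and glycosyltransferases of neutrophil adhesion, 7 were higher and 14 lower (median -0.03, adjusted p = 0.498). SELPLG, the P-selectin ligand through which the bacterium binds human neutrophils, had signals of 588 ± 78.5 and 458 ± 59.8 (SD, n = 3), with differences of -0.56, -0.58 and 0.06 in pairs 1, 2 and 3. FUT7, a fucosyltransferase that modifies that ligand, differed by -0.27 ± 0.20, CXCR4 by -0.26 ± 0.14 and ITGAL by 0.50 ± 0.34 (log2, SE).

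**Figure D3:**
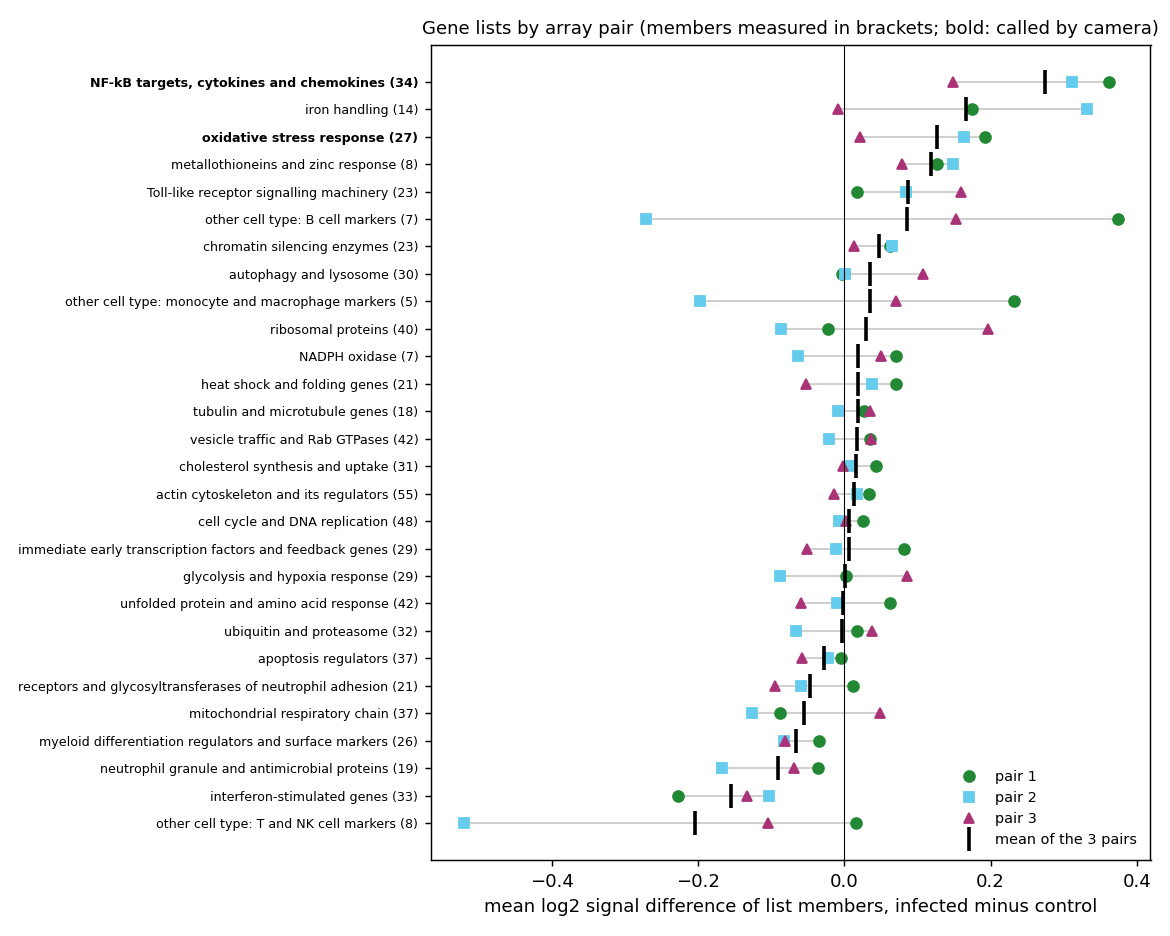
Mean log2 signal difference (infected minus control) of the measured members of the 28 tested gene lists, with 1 marker per array pair, a black bar for the mean of the 3 pairs and the number of measured members in brackets. The inflammatory list lies at 0.36, 0.31 and 0.15 in the 3 pairs, and the bold names are the 2 lists called with the preset correlation.

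Myeloid genes showed no list that passed. Of 26 differentiation regulators and surface markers, 11 were higher and 15 lower (median -0.04, adjusted p = 0.753), among them MEIS1, a homeobox gene of early progenitors (-1.17 ± 0.45, log2 and SE), CEBPD (-0.25 ± 0.16) and CSF1R, the receptor of macrophage colony-stimulating factor (0.40 ± 0.21). Of 19 granule and antimicrobial proteins, 7 were higher and 12 lower (median -0.06, adjusted p = 0.804). MPO, the main peroxidase of primary granules, stood at 27190 ± 1407 and 29260 ± 976 (SD, n = 3), where 1 of its 2 probe sets pointed the other way, and SERPINB1, an inhibitor of neutrophil proteases, differed by -0.27 ± 0.13 (log2, SE). Of 37 apoptosis regulators, 16 were higher and 21 lower (median -0.04, adjusted p = 0.498). MCL1, which protects cells from apoptosis, differed by 0.24 ± 0.12 with 3 of 5 probe sets in that direction, BCL2A1 by 0.05 ± 0.28 and BAK1, which promotes apoptosis, by -0.41 ± 0.23 (log2, SE).

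Immediate early genes went both ways. Of 29 measured, 17 were higher and 12 lower (adjusted p = 0.882), with a median of 0.03 that was -0.04 with median centring. EGR3 stood at 108 ± 19.7 in control and 227 ± 81.6 in infected cells, EGR1 at 4028 ± 1922 and 2362 ± 496 (SD, n = 3), and both had an adjusted p of 1 in limma. EGR1 differed by -0.88 in pair 1, -1.04 in pair 2 and 0.00 in pair 3. DUSP5 differed by 0.55 ± 0.33 and FOS by -0.57 ± 0.40 (log2, SE).

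Iron handling genes numbered 10 higher and 4 lower of 14 (median 0.09, adjusted p = 0.108). In fry the adjusted p was 0.754 for change in 1 direction and 0.0224 for change in either direction, where the other 27 lists had 0.798 to 0.968. Adjusted over the list alone, 0 members passed without a block and 1 with the replicate block. Without control array 3 the list was called as higher (camera, adjusted p = 0.0158, or adjusted p = 0.719 with an estimated correlation, range over the alternatives 0.0158 to 0.982). HMOX1 is also a member of it. HFE, which regulates iron uptake, had signals of 121 ± 18.3 and 226 ± 16.2 (SD, n = 3), but 2 of its 4 probe sets pointed the other way, and the ferritin light chain FTL differed by 0.09 ± 0.10 (log2, SE). The metallothionein list had 5 of 8 members higher (adjusted p = 0.39) and a median of 0.02 that was -0.05 with median centring, among them MT1F (0.76 ± 0.26), MT1H (0.45 ± 0.21) and MT2A (0.21 ± 0.17).

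Few markers of other cell types had signals above the filter. Of 22 T and NK cell markers 8 were measured, 2 higher and 6 lower (median -0.22, adjusted p = 0.0973), including CD3D at 1269 ± 152 and 977 ± 117 and CD4, which myeloid cells also express, at 1594 ± 81.8 and 1302 ± 191 (SD, n = 3). Of 15 B cell markers 7 were measured, 4 higher and 3 lower (adjusted p = 0.92), with a median of 0.07 although the test pointed to lower, and CD79B differed by -0.56 ± 0.20 (log2, SE). Of 16 monocyte and macrophage markers 5 were measured, 2 higher and 3 lower (adjusted p = 0.779), with a median of -0.01 and a mean of 0.03 (the median was 0.000133 after cyclic loess) and FCN1 at 0.23 ± 0.24. The 4 measured erythroid and platelet markers, with ITGA2B at 0.09 ± 0.16, and the 4 measured epithelial, fibroblast and endothelial markers, with PECAM1, which myeloid cells also express, at 0.44 ± 0.31, were too few to test. Of the latter, 1 passed adjusted over the list alone with the replicate block and 0 without it. Of the tested probe sets, 2 of 3 for ITGA2B and 4 of 5 for PECAM1 went in the direction given.

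Other groups had adjusted p-values from 0.39 to 0.978. The Toll-like receptor list had 16 of 23 members higher (adjusted p = 0.498, median 0.06, or -0.01 with median centring), including IRAK2 at 0.35 ± 0.30 (log2, SE). Actin genes numbered 30 higher and 25 lower (adjusted p = 0.779) with ACTB at 0.16 ± 0.12, and tubulin genes 11 higher and 7 lower (adjusted p = 0.779). Sterol genes numbered 17 higher and 14 lower (adjusted p = 0.882) with SC5D at -0.18 ± 0.12. Heat shock genes numbered 15 higher and 6 lower (adjusted p = 0.39) with HSP90AB1 at 0.14 ± 0.08 (2 of 3 probe sets in that direction). Genes of the unfolded protein and amino acid responses numbered 24 higher and 18 lower (adjusted p = 0.835), with a median of 0.04, a mean of -0.00235 and TRIB3 at -0.23 ± 0.18. Vesicle genes numbered 24 higher and 18 lower (adjusted p = 0.917), lysosome and autophagy genes 16 and 14 (adjusted p = 0.835), cell cycle genes 27 and 21 (adjusted p = 0.92) with KIF20A at -0.25 ± 0.17, and glycolysis genes 18 and 11 (adjusted p = 0.779) with PKM at 0.18 ± 0.15. Chromatin silencing genes numbered 16 higher and 7 lower (adjusted p = 0.39) with EZH2 at 0.18 ± 0.13, and proteasome genes 14 higher and 18 lower (adjusted p = 0.978). Of these groups, the chromatin list had a median of 0.08 and the proteasome list of -0.01, and the medians of the rest lay between 0.01 and 0.06, within the common shift of median centring.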

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

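The tests of shared variation within a number, of RNA degradation and of members moving together were chosen after the result they bear on was seen.

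A control probe set outside the comparisons was higher in infected arrays. The 3' probe set for the Bacillus transcript phe, a spike-in control, had signals of 37.0, 24.3 and 54.6 in control arrays and 81.6, 78.6 and 74.3 in infected arrays, a log2 difference of 1.09. These signals are dim. A second 3' probe set for phe had 79.8, 20.7 and 12 in control and 11.3, 51.9 and 96.1 in infected arrays, which overlap, and the other 4 phe probe sets lay between 2.0 and 55.8. The first was the 1 of 62 control probe sets with all 3 infected arrays above all 3 control arrays, while 3 of 62 had all infected arrays below all control arrays. Of these, 2 are dim: a 3' probe set for lys (-2.49, where another 3' lys probe set had 0.08) and one for trp (-0.65). The bright one is the 5' probe set for 18S ribosomal RNA, at 9590, 4314 and 4260 in control and 2817, 4196 and 1844 in infected arrays (-1.005). Its middle and 3' probe sets had lower means too (-0.45 and -0.36), but the groups overlapped. Chance puts about 1 in 20 on each side.

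Fewer probe sets had an unadjusted p under 0.05 (2.08%) than the 5% that independent noise gives. Noise of dim probe sets was argued against, since the share was 1.6% among the top 30% by mean signal. Variation shared by arrays of the same number may account for it, since the share was 6.56% once the number entered as a block. Without a block, however, it was also 6.52% without infected array 3 and 5.72% with array weights. With any other single array left out it was 1.42% to 2.86%. The tables therefore do not tell shared variation from a wide spread of infected array 3 alone.

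HMOX1, EGR1, SLC7A11 and both called lists had smaller differences in pair 3 than in pairs 1 and 2, and are set together here after this was seen. Others had their largest difference in pair 3, among them CXCL8 (0.24, 0.34 and 0.52), SMDT1, MAPK11, COG4, SPATA32, SENCR and MIR1915HG. Of 131 genes chosen by the naming rule, the difference was smallest in size in pair 3 for 42 and largest there for 51. For the 100 highest and 100 lowest probe sets by pair 1, taken from the top 30% by signal, the high set exceeded the low set by 0.37 on the log2 scale in pair 2 (random sets matched on signal -0.12 to 0.13) and by 0.17 in pair 3 (-0.12 to 0.11). For sets chosen by pair 2 the values were 0.33 in pair 1 and -0.00476 in pair 3. Sets chosen by pair 3 gave 0.0363 in pair 1 (random sets -0.0931 to 0.1) and 0.0823 in pair 2 (-0.132 to 0.118). Both lay inside the random ranges. The value of 0.17 lay above its random range, but its bootstrap range was -0.00401 to 0.255, so its sign is not settled. The tables leave open whether infected array 3 carries no change of this kind, because values inside a random range do not show that a change is absent. Scaling was argued against, since the higher value measured in pair 3 was 0.133 after quantile normalization. So was RNA degradation, since the 3' to 5' ratios of the number 3 arrays did not exceed the highest of the others (largest excess -0.111). Labelling and hybridization were not tested and stay open, and infected array 3 had the highest maximum signal (87898, against at most 69314 in the others). EGR1 stood at 5110, 5166 and 1809 in control and 2771, 2505 and 1810 in infected arrays, and SLC7A11 at 1635, 1561 and 2545 in control and 3029, 2524 and 2716 in infected arrays. In both, control array 3 lies apart from its group's other arrays, toward the infected level or past it, which fewer infected cells in infected array 3 would not give. For EGR1, infected array 3 also lies below the other infected arrays. HMOX1 stood at 1214 and 1215 in the number 3 arrays, between the other control (661 and 693) and infected arrays (2366 and 2133). These 3 genes decide nothing for the rest, and infection, which the design names, was not tested as a source.

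For the rise of the inflammatory list, the tables argue against a few variable members as the cause. Without CXCL10, CSF1 and TNFAIP2, the 3 largest increases, its adjusted p was 0.00169 (camera at the preset correlation). The mean moderated statistic of the 31 members left was 0.77, outside the range of -0.31 to 0.31 that held 95% of 10000 random lists matched on signal and spread. Neither value allows for members that move together, and the shortened list was not tested with an estimated correlation. Members that move together irrespective of infection stay open as an explanation. The estimated correlation of the members was 0.0881, above the range of -0.03 to 0.08 of 1000 matched random lists, and the adjusted p was 0.666 with it. That adjusted p cannot decide by itself, because this setting had little power in the simulations. There a true shift of 0.3, with noise drawn separately for each gene, gave adjusted p-values of only 0.0335 and 0.102 (camera). Of the 9 other splits of the arrays 3 also called the list (smallest adjusted p 0.0019, against 2.31e-05 for the real split), 2 of them with both number 3 arrays on 1 side. Of the 3 others that, like the real split, part all pairs, 1 called it (adjusted p = 0.00998). Infection, which the design names, remains open beside it. CSF1 is named only because it was left out there.

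The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 0 probe sets, so all 10 splits had to call at least as many and that count decides nothing. The highest of the others called 335, for the split that sets control array 1 and infected arrays 1 and 2 against control arrays 2 and 3 and infected array 3. A split that calls so many points to a structure of the samples. Here both number 3 arrays lie on 1 side with control array 2, apart from infected array 2. Of the 4 splits that keep the number 3 arrays together, it alone called any probe set, so their standing apart does not account for the count by itself. The real split called 2 lists, 7 of the 10 splits called at least as many, and the highest other called 9, also with both number 3 arrays together. The 3 others that part all pairs called 3, 1 and 1 lists. Among the 4 splits that part all 3 pairs, the real split had 1790 probe sets with an unadjusted p under 0.05 in the fit with the block, and the highest other had 1640.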

How the results depend on the processing

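The fits without both number 3 arrays and those combining 2 settings were chosen after the data were examined. The arrays are 3 per group, and signal over background was not used, so dim probe sets limit what the fits resolve. Camera takes no robust variance setting, so that alternative was not run for lists. No probe set was called (0) with any alternative fixed before the data were examined. The replicate block changed 0 calls of probe sets and 1 call of a list (the respiratory chain). Adjusted over the list alone, members passing went with it from 0 to 1 for the inflammatory, 3 for the oxidative stress, 1 for the iron and 1 for the epithelial, fibroblast and endothelial list.

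Against 568 probe sets with an unadjusted p under 0.05, the count was 1820 without a filter and 349 without probe sets that can match several transcripts (more and fewer were tested), 262 in the top 30% by signal (fewer tested), 887 without the variance trend, 1561 with array weights and 1790 with the replicate block. It was 1620 without both number 3 arrays, where 1 probe set (HMOX1, 1.73) was called, and 1867 and 1850 with the block after quantile and loess normalization, where the same 1 probe set, which matches several histone genes and was chosen after its value was seen, was called as lower. Leaving out 1 array gave 387 to 1779, the highest without infected array 3.

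Against 2 lists called, the count was 1 without a filter, without the variance trend, without probe sets that can match several transcripts and with the mean of a gene's probe sets, 6 without both number 3 arrays, and 0 with an estimated correlation, alone, with the block or without the number 3 arrays. Leaving out 1 array gave 1 to 4, and 0 in each case with an estimated correlation.

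The inflammatory list (median log2 difference 0.13) was called in every setting but those with an estimated correlation, where its median was 0.13, also with the block, and 0.24 without the number 3 arrays. The median was 0.0577 with median centring and 0.129 to 0.327 with 1 array left out. The oxidative stress list (0.05) lost its call with median centring (-0.0166), no filter (0.0497), no variance trend (0.0512), without probe sets that can match several transcripts (0.0640), with the mean of probe sets (0.00892) and with an estimated correlation (0.0512, also with the block, and 0.0667 without the number 3 arrays). Leaving out 1 array gave 0.00905 to 0.0908.

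The respiratory chain was called as lower with median centring (-0.12), array weights (-0.0934), the replicate block (-0.0499) and without both number 3 arrays (-0.0941), and ranged from -0.138 to 0.0224 with 1 array left out. Without both number 3 arrays the interferon list (-0.12) and the iron list (0.0881) were also called, and the ribosomal list was called as lower (-0.0625), the reverse of its side with all arrays. With an estimated correlation the adjusted p without these arrays was 0.687 (interferon, respiratory chain) and 0.982 (iron, ribosomal). With 1 array left out, ribosomal proteins ranged from -0.0533 to 0.0985, interferon genes from -0.132 to -0.0356, iron genes from -0.00185 to 0.13 and proteasome genes from -0.0744 to 0.0614, the last called as lower without infected array 3 (adjusted p = 0.842 with an estimated correlation). Apart from the changed numbers of probe sets tested, the cause was not tested.

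Median centring lowers all differences alike, list medians by 0.0678, so it turned the sign of the 15 of 28 that lay between 0 and 0.0678. The turned signs show only that the side of a list with so small a median depends on the scaling. Quantile normalization turned 1 and cyclic loess 1. Of 1224 values of named genes under alternatives, 18 had the opposite sign to the value with all arrays and the deposited scaling, and 1 named gene passed in some alternative.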

Other observations

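The differences of the 3 pairs were nearly unrelated across probe sets, with r of 0.07 between pairs 1 and 2, 0.00 between pairs 1 and 3 and 0.03 between pairs 2 and 3 over 27306 probe sets, which are not independent replicates. The spread of the differences (SD) was 0.48 in pair 1, 0.54 in pair 2 and 0.63 in pair 3. The sign was the same in all 3 pairs for 7773 probe sets, or 28.5%, where chance gives 25%.

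Some members of lists without a call had differences of 1 sign in all 3 pairs, and those given here were chosen after their values were seen. EGR3 was higher by 1.24, 1.21 and 0.62 on the log2 scale and MT1F by 0.71, 0.63 and 0.95 in pairs 1, 2 and 3, although a second probe set of MT1F gave -0.61, 3.02 and 0.30. MEIS1 differed by -0.88, -1.41 and -1.24 at infected signals of 67.4, 38.1 and 50.1, below the filter signal of 72.9, and CXCR4 by -0.25, -0.25 and -0.27. None passed the adjusted test in limma.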
